A study of Mus musculus with 6 samples.

How the data were processed

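Hematopoietic cells carrying a tdTomato reporter in the Hlf locus (Hlf encodes a transcription factor of blood stem and progenitor cells) were sorted from C57BL/6 mouse embryos at embryonic day 10.5. The sort kept cells positive for the reporter and for the receptor c-Kit and negative for CD45, the pan-leukocyte surface protein encoded by Ptprc. Cells came from the caudal-half region of the embryo (caudal cells) or from the yolk sac, after digestion with 0.125% collagenase for 1 h at 37 °C. Each library was made from cDNA synthesised directly from a lysate of 100 cells, per the labels' protocols. There were 3 libraries per tissue and 6 in all. The labels do not say whether the replicates came from separate embryos or pools, so p-values measure the spread between these libraries only, which may be technical. Xist, a transcript of female cells, was at 17.08 to 54.29 TPM over the 6 libraries, and the Y-linked gene Ddx3y at 6.21 to 14.35 TPM. Each library thus appears to hold cells of both sexes, and so of more than 1 embryo. Whether libraries shared a pool of embryos is not known.

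Reads were aligned with HISAT2 and quantified with StringTie against mm10, per the submitters' processing notes. The tool versions, the annotation release and the strandedness are not given in the sources used here. Each deposited table lists TPM, an abundance scaled for gene length and library, which is handled here as a signal that the authors scaled in each library, per the file headers. Every table held 2 kinds of row on that scale. Assembled loci without a gene name summed to 1000000 TPM, and named annotated genes summed to between 555230 and 684549 TPM. The column therefore exceeded that sum, and many reads were described by both kinds of row. Only annotated genes were used. They comprised 47643 gene IDs, of which 47224 were found in the GENCODE M21 annotation of GRCm38, the same assembly as mm10, ignoring ID versions. Symbols of 27 IDs had been turned into dates and were restored by gene ID. Rows with the same symbol were summed, which gave 47517 symbols. TPM keeps no read depth, so the depth of the libraries is unknown and no counting interval or detection floor can be given. Because 100 cells went into each library, values of weakly expressed genes are imprecise. PCR duplicates were not assessed here. Reads shared between overlapping genes cannot be told apart, since the use of strand is not stated.

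The tissues were compared on log2(TPM + 1) with the limma package (version 3.58.1, R 4.3.3), using a linear model of tissue, an empirical Bayes fit with a mean-variance trend and two-sided tests. Genes at 1 TPM or more in at least 3 of the 6 libraries were tested, which were 16436 genes. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. Differences are caudal minus yolk sac on the log2(TPM + 1) scale, and fold changes are taken from that scale, which understates the change of weakly expressed genes. For Hlf, Kit and Ptprc an exact two-sided permutation test was also made, whose smallest possible p with 3 against 3 libraries is 0.1.

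Before the data were examined, 38 gene lists for blood, vessel, signalling, cell cycle, metabolic and contaminating cell types were fixed, as were the tests and the alternatives unless stated otherwise. The 30 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. Named genes followed a rule fixed beforehand. It took Hlf, Kit and Ptprc, then in each direction the 10 genes with the largest difference among those passing the test with no overlap between tissues and a mean of at least 5 TPM in the higher tissue, and up to 4 members of each list by smallest p. Where fewer than 10 qualified, genes not passing the test filled the places by smallest p. Gene models without a descriptive symbol, pseudogenes and sex-linked genes were left out of the places given by size of difference. Coordinates are from GENCODE M21 on GRCm38.

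The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 10 TPM, quantile normalization, median centring, rescaling without mitochondrial, ribosomal protein and globin genes, the replicate number as a block, array weights, robust empirical Bayes and leaving out each library. Chosen after seeing the data were rescaling of the annotated genes to 1000000 TPM, the mean level of the yolk sac endoderm list as a covariate, leaving out yolk sac replicates 1 and 2 together, and camera with an estimated correlation without yolk sac replicate 2.

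The fit was tested on simulated data for the comparison of caudal with yolk sac cells, over 16436 genes with the real means and 200 changed genes. Their spread varied around a smoothed trend on the mean and was equal in all 6 libraries, while yolk sac replicate 2 stood apart in the real data. Changed genes were drawn from those with a mean log2(TPM + 1) above 2, so recovery of weakly expressed genes is not covered. The fit recovered 14.9% of genes changed by 1 on the log2 scale, 95.5% of those changed by 2 and 100% of those changed by 3, with 8 false calls among 148. Of 20 unchanged lists, 0 were called. Simulated genes varied independently of one another, so that last test does not cover lists whose genes vary together. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.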

Results

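RNA sequencing was carried out on small numbers of hematopoietic cells, taken from 2 tissues of mouse embryos. The 6 libraries fell into 3 from the caudal-half region of the embryo and 3 from the yolk sac, all at embryonic day 10.5. Between 15644 and 16975 genes reached 1 TPM in a library. The 10 most abundant annotated genes made up 27.95% to 35.09% of the annotated TPM. Entries of ribosomal RNA or like it made up 20.23% to 27.19% of the annotated TPM, so the share of the top genes may be largely ribosomal RNA. The design asked which genes differ between cells with the same surface and reporter phenotype in the 2 tissues.

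Transcripts of the 3 sorting markers were detected in all 6 libraries. Kit, the stem cell factor receptor, had a mean of 123.3 TPM ± 30.8 (SD, n = 3) in the caudal cells and 77.7 ± 30.9 (SD, n = 3) in the yolk sac. Hlf had means of 34.8 ± 8.90 and 14.6 ± 4.92 TPM, and Ptprc, which encodes CD45, had 3.87 ± 0.74 and 3.04 ± 0.63 TPM. The log2 difference of Hlf was 1.22 (SE 0.30), and its values did not overlap between the tissues. None of these 3 genes passed limma's test, with adjusted p of 0.193 for Hlf, 0.542 for Kit and 0.767 for Ptprc. With array weights, which rested mostly on caudal replicate 2 and yolk sac replicate 3, Hlf passed (adjusted p = 0.0174). Over its 19 alternatives its adjusted p was between 0.0174 and 0.722. Exact permutation p-values were 0.1, 0.1 and 0.2, where 0.1 is the smallest the design allows. In yolk sac replicate 2 alone, Hlf was at 8.95 TPM and Kit at 42.2 TPM, below the other yolk sac libraries at 17.6 and 17.3 TPM for Hlf and 91.8 and 98.9 TPM for Kit. Hlf lies on chromosome 11 (90336536 to 90390895, GRCm38), Kit on chromosome 5 (75574916 to 75656722) and Ptprc on chromosome 1 (138062861 to 138175708).

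Markers of yolk sac endoderm, the absorptive epithelium that secretes serum proteins, were abundant in 2 of the yolk sac libraries. Afp, the alpha-fetoprotein gene, was at 6110 TPM in yolk sac replicate 2, 312 TPM in replicate 1 and 0.93 TPM in replicate 3, with a mean of 0.035 TPM in the caudal cells. Apob was at 951, 40.1 and 0.30 TPM in yolk sac replicates 2, 1 and 3, and Ttr at 1480, 106 and 0.32 TPM. Embryonic globin transcripts were abundant in yolk sac replicate 2 alone, where Hba-x was at 372 TPM against 1.28 TPM in replicate 1. Across genes, the Pearson correlation of log2 values with yolk sac replicate 2 was between 0.881 and 0.917, while the other libraries correlated at 0.955 to 0.968 within a tissue and 0.944 to 0.960 between tissues. Genes are not independent replicates in these correlations. The first principal component, with 46.9% of the variance, set yolk sac replicate 2 apart from the rest. On the second, with 18.09%, caudal replicate 3 lay apart at -45.92, against -5.229 to 28.83 for the other libraries.

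**Figure D1:**
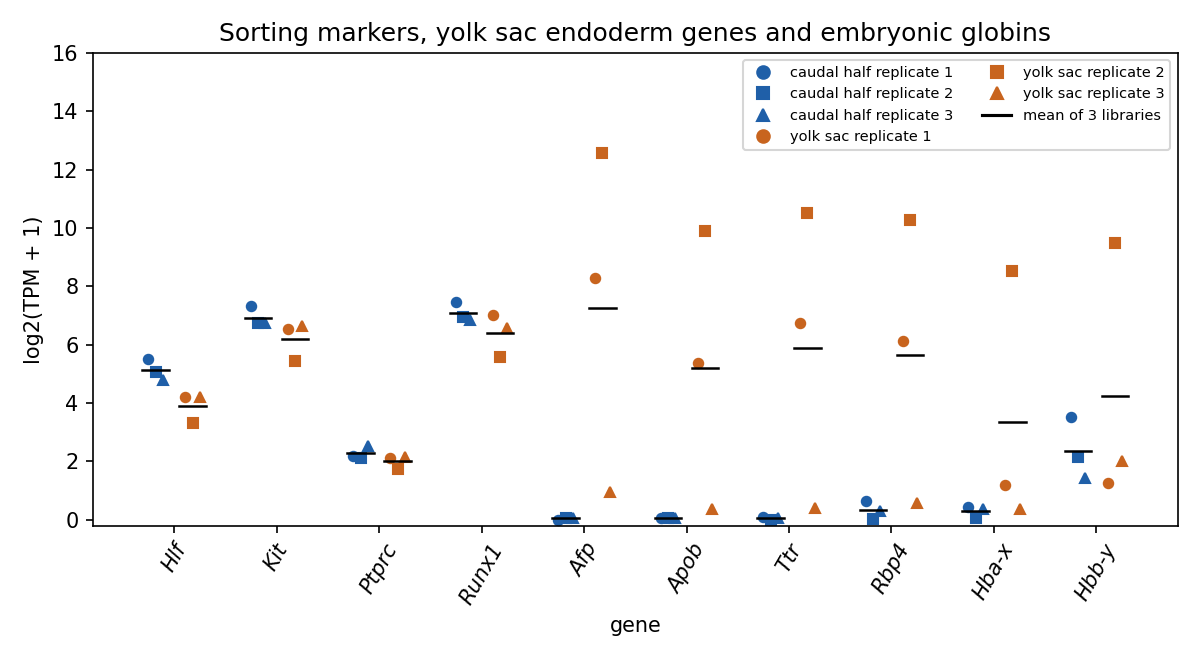
Level of sorting markers (Hlf, Kit, Ptprc), the blood transcription factor gene Runx1, yolk sac endoderm genes (Afp, Apob, Ttr, Rbp4) and embryonic globin genes (Hba-x, Hbb-y) in each library, as log2(TPM + 1); points are libraries and bars are means of 3 libraries. Afp reached 6110 TPM in yolk sac replicate 2 and 312 TPM in replicate 1, and stayed at 0.93 TPM in replicate 3.

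Acta2, Vwf, Gja5, Nrp1 and Gfi1 were among the genes most strongly higher in the caudal cells. Acta2, which encodes smooth muscle actin, was at 32.8 TPM ± 5.84 (SD, n = 3) in the caudal cells and 1.60 ± 0.84 (SD, n = 3) in the yolk sac, a log2 difference of 3.73 (SE 0.28, limma adjusted p = 0.00309). Vwf, the gene of von Willebrand factor, was at 33.8 against 2.20 TPM (log2 difference 3.56, SE 0.37, adjusted p = 0.0114). Gja5, which encodes an arterial gap junction protein, was at 11.7 ± 2.71 against 0.060 ± 0.017 TPM (log2 difference 3.56, SE 0.24, adjusted p = 0.00309). Nrp1, a receptor for semaphorins and VEGF, was at 16.5 against 0.56 TPM. Gfi1, a transcriptional repressor that acts in the transition from endothelium to blood, was at 23.1 ± 5.63 against 1.82 ± 0.81 TPM, with a log2 difference of 3.12 (SE 0.30, adjusted p = 0.0114). The cardiac actin gene Actc1 (10.6 against 0.15 TPM), the myosin light chain gene Myl9 (9.37 against 0.21 TPM), the fibrillin gene Fbn2 (14.5 against 1.13 TPM), the endothelial transcription factor gene Sox7 (11.2 against 0.72 TPM) and the adhesion receptor gene Adgrf5 (17.7 against 1.77 TPM) completed the 10 largest differences, with adjusted p between 0.00309 and 0.0238. Acta2 belongs to the mesenchyme and smooth muscle list, of which 1 of 6 tested genes passed and which did not pass camera (adjusted p = 0.0878). That list passed without yolk sac replicate 2 (0.0181, and adjusted p = 0.52 with an estimated correlation). Acta2 lies on chromosome 19 (34241090 to 34255590), Vwf on chromosome 6 (125546774 to 125686679), Gja5 on chromosome 3 (96904693 to 97077416), Nrp1 on chromosome 8 (128358604 to 128503363) and Gfi1 on chromosome 5 (107716657 to 107726036). Exons of Gja5, Nrp1, Gfi1 and Fbn2 overlap those of Gpr89, Mir1903, A430072P03Rik and Gm26507, so that their values are less certain.

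Few genes were higher in the yolk sac cells. Lyve1, a hyaluronan receptor of lymphatic endothelium and macrophages, was at 12.98 TPM ± 4.87 (SD, n = 3) in the yolk sac and 2.38 ± 0.72 (SD, n = 3) in the caudal cells, a log2 difference of -2.02 (SE 0.31, limma adjusted p = 0.0459). Tfec, a transcription factor gene of the MITF family, was at 8.52 against 1.61 TPM (adjusted p = 0.0338). Sec11c, a signal peptidase subunit (33.2 against 9.59 TPM), Galnt1, a glycosyltransferase (29.7 against 9.95 TPM), and Aspscr1, a tether of glucose transporter vesicles (18.6 against 6.83 TPM), also passed, with adjusted p of 0.0485, 0.0364 and 0.0393. Sec11c passed in 1 of its 19 alternatives, with adjusted p between 0.0018 and 0.328. The mannose receptor gene Mrc1 passed at a low level, 2.82 against 0.17 TPM (adjusted p = 0.0192). Genes that filled the remaining places did not pass the test. They were Hibadh, Fam188a, Clec1b, Car2 and Pros1, with adjusted p between 0.0572 and 0.082. Clec1b (adjusted p = 0.0218), Car2 (0.0154) and Pros1 (0.0167) passed without yolk sac replicate 2, while Tfec (0.0565), Galnt1 (0.0544) and Sec11c (0.0855) did not. Hibadh passed in 5 and Fam188a in 2 of 19 alternatives, and over the alternatives the adjusted p of these 5 genes was between 0.00107 and 0.396. Car2, a carbonic anhydrase of red cells, was at 97.2 against 38.1 TPM, and Clec1b, a platelet receptor, at 11.9 against 2.06 TPM. Lyve1 lies on chromosome 7 (110850607 to 110863239) and Tfec on chromosome 6 (16833373 to 16898441). Exons of Aspscr1, Hibadh and Clec1b overlap those of Gm17178, Gm24355 and Clec9a. Such overlaps are also found for some genes named below, such as Dll4 (Gm14207), Ephb4 (Zan), Mest (Copg2) and Igf2 (Gm49394 and Igf2os).

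**Figure D2:**
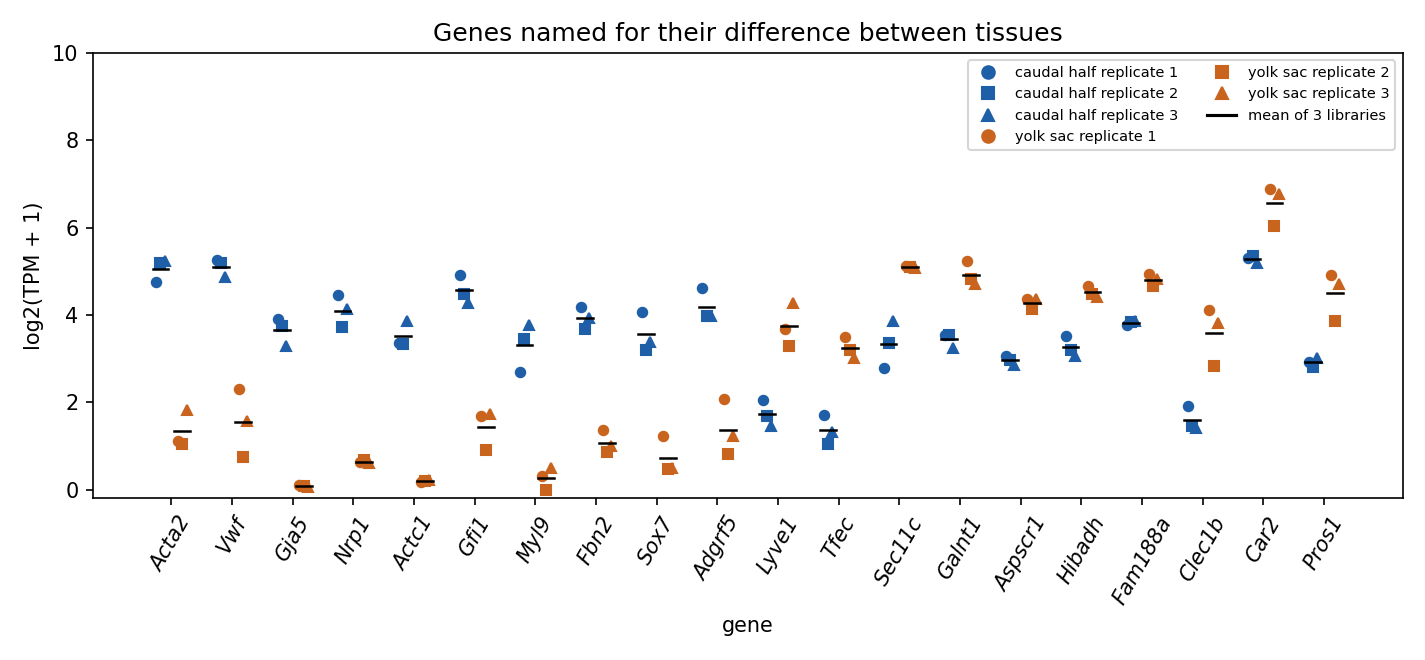
Level in each library, as log2(TPM + 1), of the 10 genes named as higher in the caudal cells (Acta2 to Adgrf5) and the 10 named toward the yolk sac (Lyve1 to Pros1), where the last 5 did not pass the test; points are libraries and bars are means of 3 libraries. The 3 values of one tissue lie above the 3 of the other for each gene.

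In total 57 genes were higher in the caudal cells and 6 were higher in the yolk sac among 16436 tested with limma. The 63 genes that passed showed no overlap between tissues, as did 2572 of all tested genes (15.6%, against 10% by chance). The count depended on single libraries. Without caudal replicates 1, 2 or 3 it was 5, 19 and 2 genes higher in the caudal cells and 0, 1 and 0 in the yolk sac, and without yolk sac replicates 1 or 3 it was 17 and 16, and 1 and 2. Without yolk sac replicate 2, which held the most endoderm transcripts, it was 55 and 6, of which 41 and 3 were the genes called with all libraries. Gja5 and Actc1 passed whichever library was left out. With a pseudocount of 5 the counts were 37 and 2, with a filter at a mean of 10 TPM 8 and 0, and with no filter 0 and 0 by limma, where 2547 genes had an unadjusted p under 0.05.

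Endothelial, arterial and Notch genes had positive differences in the caudal cells, and these 2 lists passed camera with the preset correlation but not with an estimated one. Of 25 tested endothelial genes, 5 rose and 20 did not pass, while 23 passed when adjusted over the list alone, and all 25 had positive differences (median 1.44). Cdh5, the VE-cadherin gene, was at 97.6 against 16.6 TPM (limma adjusted p = 0.0114), and Clec14a (8.43 against 0.94 TPM) and Mmrn2 (12.4 against 1.86 TPM) also passed. Camera gave the endothelial list an adjusted p of 2.61e-22 with the preset correlation, but adjusted p = 0.482 with an estimated correlation, and fry, which does not compare a list with other genes, gave 0.0589. Of 19 arterial and Notch genes, 6 rose, 17 passed when adjusted over the list alone and all 19 were positive (median 1.39). They included Hey1, a Notch target (7.91 against 0.48 TPM, adjusted p = 0.0114), and the Notch ligand gene Dll4 (6.51 against 0.65 TPM, adjusted p = 0.0199). That list had an adjusted p of 9.17e-25 by camera, and adjusted p = 0.404 with an estimated correlation, while fry gave 0.00583. Among 8 venous and lymphatic genes Lyve1 alone passed, toward the yolk sac, and 3 and 2 members passed over the list alone toward the caudal cells and the yolk sac (camera adjusted p = 0.876). Ephb4, a venous receptor gene, was at 11.6 against 5.14 TPM (limma adjusted p = 0.344) and passed toward the caudal cells without yolk sac replicate 2 (adjusted p = 0.0496). It passed in 2 of its 18 alternatives, with adjusted p between 0.00568 and 0.728.

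Stem cell transcription factor genes were positive in 25 of 27 cases (median 0.69), of which only Gfi1 passed over all genes and 6 passed when adjusted over the list alone. Hoxa9 was at 15.7 against 3.14 TPM (adjusted p = 0.0818) and Zfp521 at 25.7 against 9.25 TPM (adjusted p = 0.09). The camera adjusted p was 2.84e-08, with adjusted p = 0.571 with an estimated correlation. Without yolk sac replicate 2 the median was 0.29. Of 22 stem and progenitor surface protein genes, Cdh5 and Procr (11.9 against 1.58 TPM, limma adjusted p = 0.0364) rose, 3 passed over the list alone and 18 were positive (median 0.64). The median was 0.26 without yolk sac replicate 2, and Procr did not pass (adjusted p = 0.0556). In that fit 5 members passed over the list alone toward the caudal cells and 2 toward the yolk sac. Camera gave 0.000318, adjusted p = 0.601 with an estimated correlation, and 0.432 with the level of endoderm genes as a covariate. Cdh5, Tek, Esam, Emcn, Cd34 and Robo4 of this surface protein list are also in the endothelial list, so the lists are not separate evidence. The 4 Hox genes of groups 5 to 13 that were tested (Hoxa5, Hoxa7, Hoxa9 and Hoxa10, on chromosome 6) had positive differences between 1.10 and 2.06. None passed over all genes and 4 passed when adjusted over the list alone, too few members for camera. Exons of Hoxa7 and Hoxa9 overlap Hoxaas3 and Mir196b.

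BMP and TGF-beta, Wnt, imprinted, adhesion and immediate early lists were also toward the caudal cells by camera with the preset correlation but not with an estimated one. Some members, such as Eng and Acvrl1 (BMP and TGF-beta) and Cxcr4 and Icam2 (adhesion), are also in the endothelial or the arterial and Notch list. Of 21 BMP and TGF-beta genes, Bmper, an extracellular BMP modulator, rose (4.58 against 0.29 TPM, limma adjusted p = 0.0151) and 7 passed over the list alone, with a camera adjusted p of 5.53e-05. With an estimated correlation adjusted p = 0.482. Of 10 Wnt targets and receptors, Fzd1 rose (5.42 against 1.03 TPM, adjusted p = 0.0314), with a camera adjusted p of 0.0238 and adjusted p = 0.601 with an estimated correlation. The Wnt list did not pass without caudal replicate 1 (adjusted p = 0.0619), yolk sac replicate 1 (0.201) or yolk sac replicate 3 (0.283). Without yolk sac replicate 2 it passed (camera adjusted p = 1.75e-05, and adjusted p = 0.52 with an estimated correlation). Its median was then 0.689, against 0.488 with all libraries. Of 20 imprinted genes, Mest rose (50.1 against 9.92 TPM, adjusted p = 0.0482) but passed in only 1 of its 19 alternatives (adjusted p between 0.00676 and 0.264), and Igf2 was at 287 against 124 TPM (adjusted p = 0.0594). The imprinted list had a camera adjusted p of 0.0225 and adjusted p = 0.571 with an estimated correlation. It did not pass without caudal replicate 3 (0.0924), yolk sac replicate 1 (0.158) or yolk sac replicate 3 (0.617). Nor did it pass with no filter (0.129), with a filter at a mean of 10 TPM (0.0845) or with annotated genes rescaled (0.118). Without yolk sac replicate 2 the imprinted list passed (camera adjusted p = 8.65e-08, and adjusted p = 0.52 with an estimated correlation). Its median was then 0.685, against 0.324 with all libraries. Among 19 adhesion and homing genes 0 passed over all genes and 4 over the list alone, with Cxcr4 at 11.2 against 1.60 TPM (adjusted p = 0.0594). Camera gave 0.0144, adjusted p = 0.601 with an estimated correlation, 0.0551 with array weights and 0.133 without yolk sac replicate 2. In the immediate early and handling stress list, 0 of 26 genes passed and 23 were positive, with Nr4a1 at 49.1 against 22.7 TPM (adjusted p = 0.155). Its camera adjusted p was 0.0126, adjusted p = 0.785 with an estimated correlation, 0.694 with array weights, 0.072 without caudal replicate 3 and 0.634 without yolk sac replicate 2. Among 8 retinoid genes Cyp26b1, which degrades retinoic acid, rose (21.6 against 3.03 TPM, limma adjusted p = 0.0478) but passed only in 4 of its 19 alternatives (adjusted p between 0.00428 and 0.264). The retinoid list did not pass (camera adjusted p = 0.164), and passed without yolk sac replicate 2 (0.0104, and adjusted p = 0.52 with an estimated correlation).

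Genes of the G2 and M phases, oxidative phosphorylation, the mitochondrial genome and cholesterol synthesis were toward the yolk sac by camera with the preset correlation but not with an estimated one, with small differences and 0 genes passing singly. Of 30 genes of the G2 and M phases, 3 were positive (median -0.21). Birc5 was at 37.6 TPM in the yolk sac and 26.0 TPM in the caudal cells (limma adjusted p = 0.391). Camera gave this list 3.84e-08 and adjusted p = 0.482 with an estimated correlation, while the G1 and S phase list, with 25 of 30 genes positive (median 0.176), did not pass (camera adjusted p = 0.305). The G1 and S phase list had 19 positive (median 0.04) without yolk sac replicate 2, and camera's direction was then toward the yolk sac (adjusted p = 0.877). Of 73 nuclear oxidative phosphorylation genes 11 were positive (median -0.24, camera adjusted p = 4.69e-11, and adjusted p = 0.571 with an estimated correlation). Of 13 mitochondrially encoded genes 0 were positive (median -0.26, camera adjusted p = 0.000115, and adjusted p = 0.601 with an estimated correlation). Without yolk sac replicate 2 the mitochondrially encoded median was -0.06 and its adjusted p 0.151. Cholesterol synthesis genes were positive in 4 of 22 cases (median -0.15, camera adjusted p = 0.000509, and adjusted p = 0.482 with an estimated correlation). That list did not pass without caudal replicate 1 (0.083) or yolk sac replicate 2 (0.0616).

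**Figure D3:**
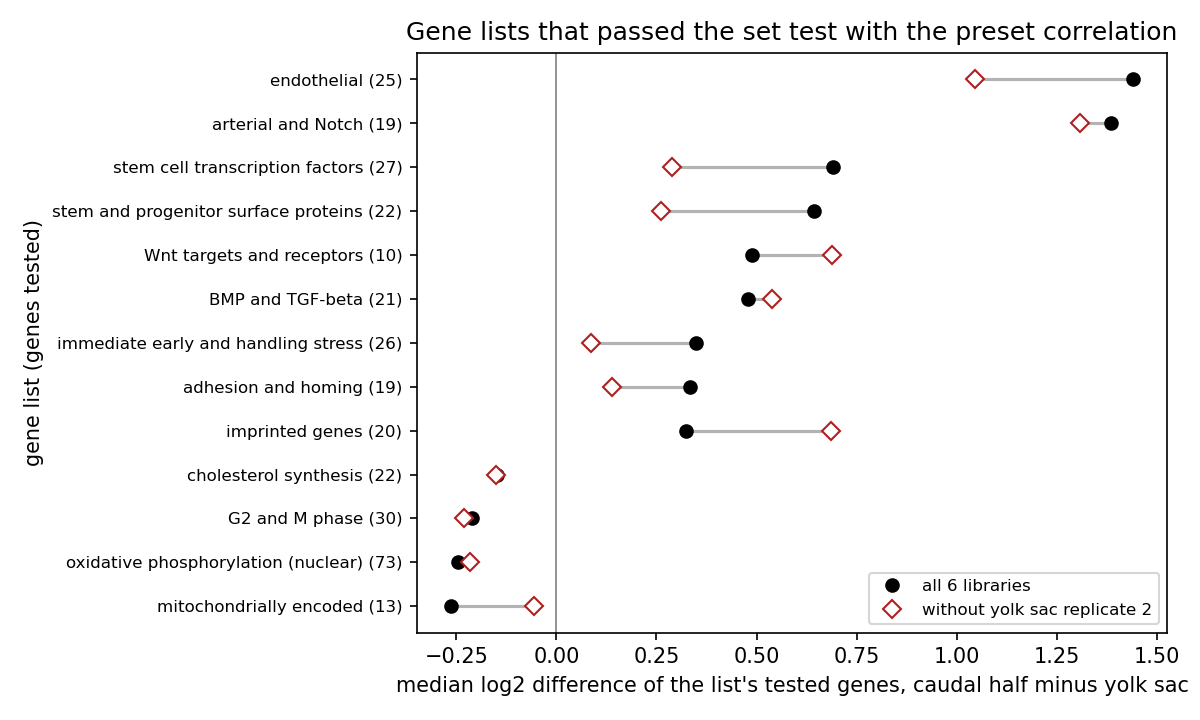
Median log2 difference, caudal minus yolk sac, of the tested genes of the 13 lists that passed camera with the preset correlation, with all 6 libraries (black) and without yolk sac replicate 2 (open red); numbers in brackets are genes tested. The endothelial median was 1.44 with all libraries and 1.05 without yolk sac replicate 2, and the stem cell transcription factor median 0.69 and 0.29.

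Blood lineage lists did not pass camera. The adjusted p was 0.13 for erythroid, 0.334 for megakaryocyte, 0.561 for granulocyte and monocyte, 0.0881 for macrophage and 0.424 for lymphoid genes. Of 4 tested mast cell and basophil genes none passed, with Cpa3 at 5.43 TPM in the yolk sac against 1.70 TPM in the caudal cells (limma adjusted p = 0.09). Without yolk sac replicate 2 the megakaryocyte list was toward the yolk sac (camera adjusted p = 0.000251, and adjusted p = 0.618 with an estimated correlation), and over the list alone 11 of 19 members passed toward the yolk sac and 3 toward the caudal cells. Vwf, also a member, was higher in the caudal cells. The ribosomal protein list did not pass (camera adjusted p = 0.431), and without yolk sac replicate 2 it was toward the yolk sac (camera adjusted p = 0.0367, and adjusted p = 0.972 with an estimated correlation). Interferon response, inflammatory signalling, cell cycle inhibitor, glycolysis, hypoxia, fetal programme and sex-linked lists did not pass, with adjusted p between 0.248 and 0.901. In total 13 of 30 lists passed camera with the preset correlation, 9 toward the caudal cells and 4 toward the yolk sac. With an estimated correlation 0 passed, the smallest adjusted p being 0.404, and 1 had an unadjusted p under 0.05. Without yolk sac replicate 2 also 13 lists passed with the preset correlation and 0 with an estimated one, and 9 of them passed with all libraries too.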

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

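The alternatives chosen after seeing the data were the rescaled annotated genes, the endoderm covariate, leaving out yolk sac replicates 1 and 2 together, and the estimated correlation without yolk sac replicate 2. The counts of genes higher in the caudal cells and in the yolk sac by limma were 57 and 6. They became 37 and 2 with a pseudocount of 5, 8 and 0 with a filter at a mean of 10 TPM (7346 genes tested), 17 and 1 with the endoderm covariate, 13 and 0 without yolk sac replicates 1 and 2, and 774 and 182 with array weights. The endoderm level was high only in yolk sac replicates 1 and 2. That covariate thus overlaps with tissue and may take up part of a tissue difference. In the fit without yolk sac replicates 1 and 2 the lone yolk sac library is assumed to vary like the caudal libraries. Array weights were 4.44 for caudal replicate 2 and 3.24 for yolk sac replicate 3. For the other libraries they were between 0.227 (yolk sac replicate 2) and 0.83 (yolk sac replicate 1). That fit thus rested mostly on 1 library per tissue, and all 63 reported genes passed in it. With no filter 0 and 0 of 33730 genes passed, and 2547 had an unadjusted p under 0.05. With the replicate block the counts were 0 and 0, with 1611 genes at an unadjusted p under 0.05. The deviations of libraries with the same replicate number correlated at 0.019, -0.021 and -0.003, and those with other numbers at -0.029 to 0.034. With 3 libraries per tissue and yolk sac replicate 2 set apart, these values cannot show whether libraries were paired. The labels do not say whether the same embryos gave both tissues, so pairing is unknown. The cause of these shifts was not tested. Leaving out each library gave 2 to 55 genes higher in the caudal cells, 0 to 6 higher in the yolk sac and 11 to 13 lists. The 63 reported genes kept their sign wherever they were tested, and their number passing and shared was 5, 18 and 2 without caudal replicates 1, 2 and 3 and 15, 44 and 16 without yolk sac replicates 1, 2 and 3. The other scalings gave 48 to 60 genes higher in the caudal cells.

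Of the 63 genes, those named in the text that passed in the fewest alternatives were Mest and Sec11c (1 of 19), Cyp26b1 (4 of 19) and Procr and Mmrn2 (6 of 18). Of its 19 alternatives Hlf passed with array weights alone (adjusted p 0.0174).

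The 13 lists became 0 with an estimated correlation (smallest adjusted p 0.404, and 1 list with an unadjusted p under 0.05) and 0 with the estimated correlation without yolk sac replicate 2 (smallest adjusted p 0.52). By fry 3 lists passed, of which 2 (arterial and Notch, BMP and TGF-beta) are among the 13 and mesenchyme and smooth muscle is not, and fry does not compare a list with other genes. With the endoderm covariate the mitochondrially encoded list (adjusted p 0.792) and the immediate early list (0.516) changed direction, and the immediate early list did so without yolk sac replicates 1 and 2 (0.819). With the covariate the stem and progenitor surface (0.432), adhesion (0.29) and cholesterol synthesis (0.283) lists did not pass, nor did the mitochondrially encoded list without yolk sac replicates 1 and 2 (0.899), the immediate early (0.694) and adhesion (0.0551) lists with array weights, or the imprinted list with no filter (0.129), a filter at a mean of 10 TPM (0.0845) or annotated genes rescaled (0.118). The log2 differences of Hlf, Kit and Ptprc kept their sign under median centring and a pseudocount of 0.1. Depth is unknown for these tables, and 100 cells per library limit the precision of low values.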

Other observations

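Tests on the endoderm transcripts, on dilution, on contractile genes and the splits for genes were chosen after the results were seen. Further genes passing limma's test, named after their values were seen, were Cd24a, a glycoprotein of progenitor cells (84.3 TPM in the caudal cells against 15.5 TPM in the yolk sac), the fibrillin gene Fbn1 (6.41 against 0.39 TPM), the matrix protease genes Mmp2 (17.4 against 3.57 TPM) and Mmp14 (6.50 against 0.85 TPM), the guidance ligand genes Slit2 (23.1 against 5.02 TPM) and Sema3g (5.50 against 0.36 TPM), and the receptor gene Notch3 (7.16 against 0.82 TPM, which did not pass without yolk sac replicate 2, adjusted p = 0.0603). Mecom, a transcription factor gene of blood stem cells, was at 53.1, 32.9 and 16.5 TPM in the caudal libraries and 8.06, 1.56 and 3.83 TPM in the yolk sac libraries. It did not pass (log2 difference 2.72, SE 0.53, limma adjusted p = 0.0911). Caudal replicate 3 had 38602 assembled loci, against 27177 to 30048 in the other libraries. Of the lists for other cell types, Nes was the only neural gene tested (11.8 against 8.0 TPM), and none of 4 tested germ cell genes passed. In the somite and muscle list 2 genes were tested, Actc1 and Tcf15, with a median log2 difference of 2.32. Actc1 passed over all genes, Tcf15 (3.09 against 0.64 TPM, limma adjusted p = 0.0735) did not, and 2 passed when adjusted over the list alone. Krt8 of the epithelial list was at 7.18, 154.1 and 0.16 TPM in yolk sac replicates 1, 2 and 3, against a mean of 0.56 TPM ± 0.62 (SD, n = 3) in the caudal cells. Its level was thus carried by replicate 2, which also held the most endoderm transcripts.

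Endoderm transcripts in yolk sac replicates 2 and 1 may come from yolk sac endoderm cells or their RNA, which the gate for the reporter and c-Kit would be meant to remove. Of 27 endoderm genes in the files, 25 had a mean under 2 TPM in the caudal cells, and these summed to 15400 TPM in yolk sac replicate 2, 893 TPM in replicate 1, 5.73 TPM in replicate 3 and at most 5.08 TPM in a caudal library. The ratio of replicate 2 to replicate 1 was taken over the 21 genes at 1 TPM or more in replicate 1. It was 16.3 at the median, with an SD of 0.351 on the log2 scale, as a single source would give. Genes under 1 TPM in replicate 1 were left out, so the spread over all 25 may be larger. Carry-over of the replicate 2 library into replicate 1 is argued against by 5 globin genes. Their lowest ratio was 290, against a highest of 26.0 for those 21 endoderm genes. Expression by sorted yolk sac cells in general is argued against by the 0 of 25 genes that reached 1 TPM in replicate 3. A difference between the yolk sac libraries in how the tissue was dissected or sorted stays open and was not tested.

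Genes higher in the caudal cells could reflect dilution of yolk sac replicate 2 by other RNA, as 44 blood cell genes with a mean of at least 10 TPM were at a median of 0.459 times their level in the other yolk sac libraries there. Dilution of replicate 2 by that median could shift a difference by at most 0.374 on the log2 scale. The smallest difference among the genes that passed was 1.275. This size argues against dilution as the whole cause for the 57 genes higher in the caudal cells. Their median log2 difference was 2.06 with all libraries and 2.02 without replicate 2, with a lower quartile of 1.69. Those genes were called on the same libraries, so a median that held is no separate evidence. For the stem cell transcription factor list, the median went from 0.692 to 0.289 without replicate 2 and was 0.0161 for all genes, with 24 of 27 members positive (camera adjusted p = 9.35e-06, and adjusted p = 0.628 with an estimated correlation). Dilution of replicate 2 cannot account for the 0.289 that was left without that library. However, another of the 10 splits of the 5 remaining libraries gave a median of 0.372 in size. That split set caudal replicates 1 and 2 against caudal replicate 3 and yolk sac replicates 1 and 3. It thus still held part of any tissue difference. The splits therefore cannot measure the variation between libraries apart from tissue, and a tissue difference in this list stays undecided. In 1 of the 10 splits of the 6 libraries, the real one, 63 genes passed and the highest other split gave 1. For the lists, only the real split reached 13, and the other splits gave 6 to 10. With 10 splits no share under 0.05 can be reached.

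Contractile genes (Acta2, Actc1 and Myl9, grouped after their values were seen) higher in the caudal cells might come from mesenchymal cells in those libraries, which the gate would be meant to remove. The other 21 mesenchyme genes had a median log2 difference of 0.0866 and an upper quartile of 0.201, against a lowest of 3.04 for these 3 contractile genes, which were chosen because they passed limma's test, and none exceeded a mean of 4.23 TPM in the caudal cells. Of the 3 contractile genes only Acta2 is in the mesenchyme and smooth muscle list, while Actc1 is in the somite and muscle list. Other contractile members of the mesenchyme list, Tagln (5.01 against 1.08 TPM, log2 difference 1.479, limma adjusted p = 0.09) and Cnn1 (0.571 against 0.377 TPM, under the filter), are in neither set. Only 5 of the 21 reached a mean of 1 TPM in the caudal cells, and genes near the floor exclude nothing, so mesenchymal cells stay open. The mesenchyme and smooth muscle list did not pass camera (adjusted p = 0.0878, and adjusted p = 0.482 with an estimated correlation). It passed without yolk sac replicate 2 (0.0181, and adjusted p = 0.52 with an estimated correlation) and with fry (0.00583), which does not compare a list with other genes. Caudal replicate 1 had the least Acta2 (26.1 TPM) of the caudal libraries and the most Pdgfra (2.29 TPM), Col3a1 (1.25 TPM) and Col1a1 (0.438 TPM). Pdgfrb was highest in caudal replicate 2 (1.5 TPM) and Col1a2 in caudal replicate 3 (1.7 TPM). Mesenchyme genes thus peaked in different libraries, at low levels that decide nothing about mesenchymal cells. Other contractile cells, endothelial cells and expression by the sorted cells themselves also stay open and were not tested.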
